A study of Homo sapiens with 2 samples.

How the data were processed

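The series holds 2 libraries from 1 pool of cells of 5 tumours: a 10x Genomics 3' gene expression library and a hashtag library that counts antibody-borne tags. Per the labels' protocols, cells were stained with hashtag antibodies, combined at equal numbers, sorted for cyan fluorescent protein and sequenced on an Illumina HiSeq. The deposited values are raw UMI counts per gene or hashtag and barcode, in 1 matrix of 36601 genes and 10 hashtags by 5269 barcodes. Per the file headers the matrix was written by Cell Ranger 5.0.1, whereas the submitters' processing notes name Cell Ranger 2.1.1 with GRCh38, and this difference was not resolved. UMIs collapse copies made by PCR, and 3' counting sees mostly the ends of transcripts. Each deposited barcode held at least 501 UMIs, and how barcodes were called as cells is not given in the sources used here.

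Cells were kept with at least 1000 detected genes and at most 20% mitochondrial UMIs, thresholds set before the data were examined. This removed 1731 barcodes, 166 for few genes only, 995 for mitochondrial share only and 570 for both. The kept cells held 4.42e+07 UMIs. In the kept cells, 13.0% of UMIs came from mitochondrial genes and 12.7% from ribosomal protein genes. The labels state about 3500 genes per cell, beside a median of 3234 in kept cells and 2817 in all deposited barcodes.

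The planned hashtag rule gave a cell to its top hashtag when that had at least 10 counts and at least 3 times the second. It placed only 23 kept cells, called 3511 multiple and 4 negative, because most cells carried a pair of hashtags: the median shares of the first, the second and the third hashtag of a cell were 54.3%, 41.6% and 0.745%. A pair rule was therefore added after seeing the data. A cell went to its top pair when the second hashtag had at least 10 counts and at least 3 times the third, and pairs with at least 30 kept cells were used. All 15 such pairs joined HTO2, HTO3 or HTO4 with one of HTO5 to HTO10, and no kept cell fell in another pair. The hashtags carry numbers and no treatment names, and no label pairs them with treatments. The order of the entries in the labels, cell numbers and expression values were not used to assign treatments. The tests planned for differences between treatments were conditional on such a map and were not run. Values are given per hashed sample or as range and median.

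Doublets were sought with Scrublet as implemented in scanpy 1.11.5, which marked 0 cells and so did not work on this library. At least 10 counts of the third hashtag, with no clear pair, were seen in 389 kept cells (11.0%), which can mark droplets with cells of several samples. These were left out of values per hashed sample and kept in the clustering. Doublets within a hashed sample were not detected.

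Fixed before the data were examined were 12 response lists and 7 lists of cell type markers. List levels are summed counts over members per 10000 UMIs, with exact Poisson intervals at 95%. Where a hashed sample had 0 counts, the ratio printed is the lower bound of the exact interval with that count of 0. For the 4-fold rule below, a count of 0 was put at a floor of 3 counts. A gene or list member was called spanning when the highest hashed sample was at least 4 times the lowest and the lower bound of the ratio's interval was at least 2, among genes with a mean of at least 0.05. On simulated counts with the real sample sizes and Poisson error only, this rule called 18 of 9227 unchanged genes (0.195%). Among genes raised in 5 samples it called 3 of 50 at 2-fold, 49 of 50 at 4-fold and 50 of 50 at 8-fold. The simulation had no extra variation between cells, so these shares are not error rates for the real counts. The span rule was set after the hashtag pairs were seen. The pair rule gave 3000 of 3000 simulated cells their true pair. Those cells all had 2 strong tags over a low even background and no mixed droplets. The result therefore does not measure wrong pairs in the real data.

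For coherence, shares of cells with a UMI, relations and distributions, cells were thinned to 5000 UMIs, leaving out 269 shallower cells. Coherence is the median pairwise Spearman correlation of a list's members and its percentile among 10000 random lists matched in 30 expression bins. In simulated data, 30 genes changed together stood at the 100 percentile, and 1 of 20 unchanged lists passed the 97.5 percentile. Apart from the set changes, the simulated counts had Poisson error only, so this does not measure error rates on the real counts. Distributions were fitted with Gaussian mixtures of 1 to 3 components on log2 of the level plus 1 (scikit-learn 1.9.0), chosen by the Bayesian information criterion. Fits for sparse lists followed the zeros and are not reported. Clusters were made with scanpy from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 (leidenalg 0.10.2). Leading genes were ranked by fold among genes seen in at least 25% of a cluster's cells. No p-value was made from cells.

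Named genes followed a rule fixed beforehand: per cluster the 10 leading genes by fold, per list the 8 members of highest mean and the 4 most variable with a mean of at least 0.05, and 19 genes by name. PSME1 was named because it was an exception to a count. Some genes that the rule names are not reported here. Gene names are those of the matrix. Of its gene IDs, 34616 (94.6%) were found in GENCODE 29, a GRCh38 annotation used for coordinates, which may differ at gene ends from the one used upstream. Some list symbols were older or newer names of genes in the matrix and added no second count. Alternatives covered cell filters, hashtag rules (among them HTODemux in Seurat 5.3.0), scaling, thinning, list membership and clustering settings. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3.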

Results

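The data described tumour cells of OVCAR5, a human ovarian carcinoma line, that had been grown as tumours in immunodeficient mice, taken out, digested to single cells and exposed to cytokines in culture for 6 h. The cells carried a reporter that senses interferon gamma (IFN-gamma, the main T cell cytokine that induces antigen presentation) and were sorted for a cyan fluorescent protein, which the labels give as the mark of bystander tumour cells. The labels list 15 entries for a single pooled library. Of these, 5 were unstimulated, 5 received 10 ng/ml of tumour necrosis factor alpha (TNF, an inflammatory cytokine that acts through NF-kB), and 5 received 100 ng/ml IFN-gamma with 10 ng/ml TNF. The design thus asks how tumour cells respond to TNF alone and to both cytokines. The sources used here do not say which hashtag carried which treatment, so no value below is compared between treatments.

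The gene expression library held 5269 barcodes, of which 3538 were kept as cells. Kept cells had a median of 11555 unique molecular identifiers (UMIs, counts of single RNA molecules), 3234 detected genes and 13.1% mitochondrial UMIs. Kept cells with 1 clear pair of hashtags numbered 3144, which is 88.9% of them. Each carried 1 of the hashtags HTO2 to HTO4 together with 1 of HTO5 to HTO10, and the pairs numbered 15, as many as the entries in the labels. Each pair is treated below as 1 hashed sample with no known treatment. The hashed samples held 49 cells (HTO3+HTO5) to 630 cells (HTO3+HTO8), with a median of 147. Their total ranged from 582102 to 7324691 UMIs. Depth per cell was close among them, with median UMI counts from 10942 to 12405 and median mitochondrial shares from 12.2% to 14.7%. Levels are summed counts per 10000 UMIs, given with exact 95% Poisson intervals that cover counting error only. A ratio of the highest to the lowest hashed sample picks extremes and has no replicate check.

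Genes of the IFN-gamma response varied widely between the hashed samples. The summed level of the list was 17.3 (95% interval 16.5 to 18.2) in HTO3+HTO7 and 361 (359 to 363) in HTO3+HTO6, a ratio of 20.8, and the median of the 15 samples was 33.2. Of the 35 members with a mean level of at least 0.05, 33 spanned at least 4-fold with a lower bound of at least 2. The 2 exceptions were PSME1 and PSME2, the proteasome activator subunits, with PSME2 at 4.29 to 12.6. IRF1, a transcription factor induced early by IFN-gamma, ranged from 0.738 to 42.6, a 57.7-fold span (45.3 to 74.7). GBP1, an IFN-inducible guanylate-binding protein, spanned 88.1-fold, from 0.451 to 39.7.

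Chemokines that attract T cells through the receptor CXCR3 had wider ranges still. CXCL10 lay at 0.0859 (5 counts) in HTO3+HTO5 and at 95.9 in HTO2+HTO7, and had the highest mean level of the list. CXCL11 ranged from 0.0110 (a single count) to 15.6, a ratio of 1415 with a counting interval of 254 to 55884. CXCL9 had no count in HTO2+HTO8 and reached 2.72 in HTO3+HTO6, at least 137-fold higher by the lower bound of the interval. IDO1, the tryptophan-degrading enzyme, spanned 0.0534 to 33.9. CD274, which encodes the checkpoint ligand PD-L1, had no count in HTO3+HTO5 and stood at 2.13 in HTO2+HTO7, at least 33.6-fold higher. JAK2, a kinase of the IFN-gamma receptor, ranged from 0.0172 (a single count) to 0.743, a ratio of 43.3 with a counting interval of 7.70 to 1715, and JAK1 from 1.36 to 2.37. Of the receptor genes, IFNGR1 ranged from 0.350 to 1.14 and IFNGR2 from 0.421 to 2.00. IRF1 lies on chromosome 5 at 132481609 to 132490798 and CXCL10 on chromosome 4 at 76021117 to 76023497, both on the minus strand of GRCh38 in GENCODE 29.

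**Figure D1:**
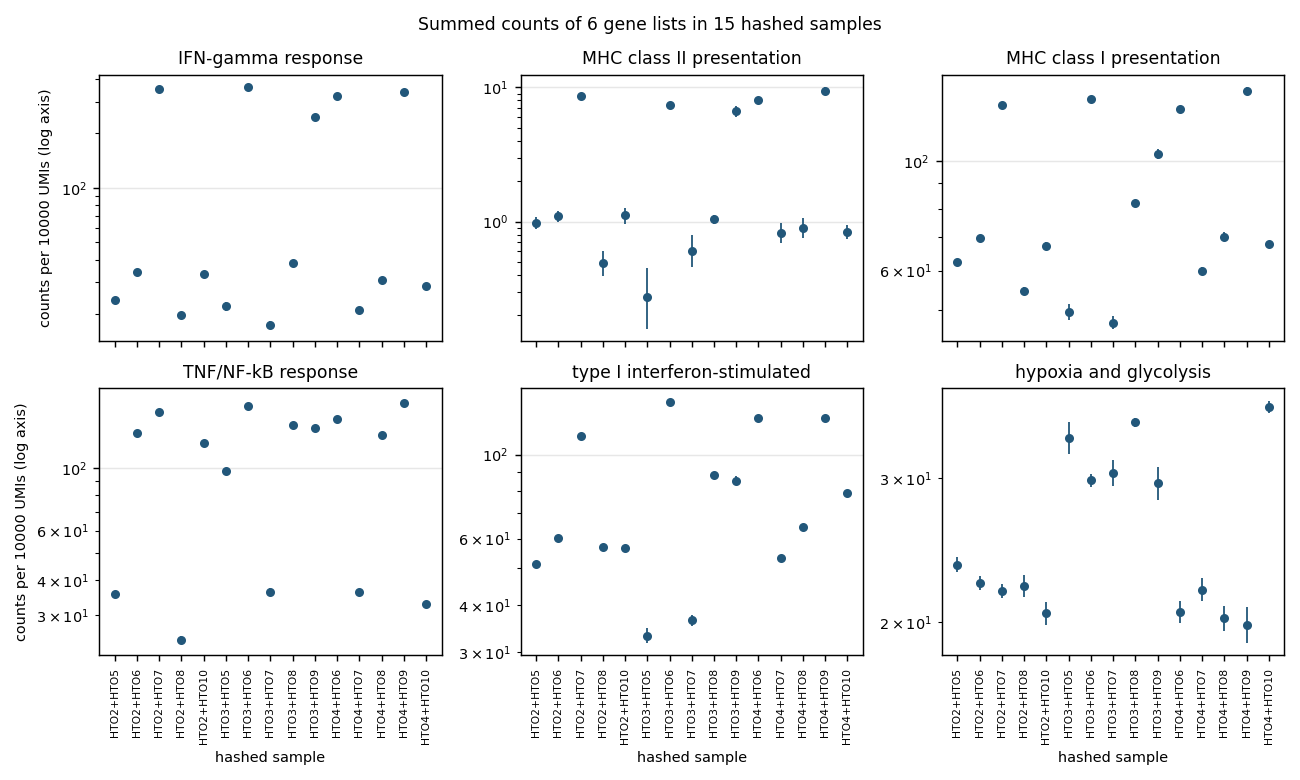
Summed counts per 10000 UMIs (log axes) of 6 gene lists in each of the 15 hashed samples, with points as levels and bars as exact 95% Poisson intervals. The IFN-gamma response ran from 17.3 to 361, the TNF/NF-kB response from 24.5 to 171, and the hypoxia and glycolysis list from 19.9 to 36.6.

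Antigen presentation genes also differed between hashed samples, class II far more than class I. The MHC class I list ranged from 47.1 to 138, a 2.94-fold span, and 9 of its 16 members met the span rule. B2M, the invariant light chain of class I, was abundant in every hashed sample and ranged from 22.8 to 65.0. HLA-E spanned 5.21-fold, while PSMB9, an immunoproteasome subunit, spanned 13.1-fold (9.21 to 19.3). Reads of the HLA genes may have been split among near-identical family members, so single HLA values are uncertain. The MHC class II list ranged from 0.275 to 9.42, and 5 of 6 members met the rule. CD74, the invariant chain, ranged from 0.103 to 5.56. CIITA, the master activator of class II transcription, had no count in HTO2+HTO8 and reached 1.24 in HTO2+HTO7, at least 62.5-fold higher. The class II span of 34.3-fold was 17.7-fold without the 4 hashed samples of fewest cells (HTO3+HTO5, HTO3+HTO9, HTO4+HTO9 and HTO3+HTO7).

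TNF and NF-kB target genes also varied between the hashed samples. The list lay between 24.5 (23.8 to 25.3) in HTO2+HTO8 and 171 (168 to 174) in HTO4+HTO9, a 6.97-fold span, with a median of 131. The span rule was met by 36 of 44 members. NFKBIA, the inhibitor that NF-kB induces as its own feedback, ranged from 1.12 to 20.1, or 17.9-fold (15.5 to 20.8). TNFAIP3, another feedback inhibitor, ranged from 0.0643 to 3.90. ICAM1, an adhesion molecule, spanned 30.5-fold and SOD2, the mitochondrial superoxide dismutase, 19.3-fold. Among secreted factors, CXCL8, a neutrophil-attracting chemokine, ranged from 0.170 to 12.9, and CCL2 from 0.0361 to 3.41. IL32 spanned 33.4-fold and LTB 103-fold (47.1 to 280). LCN2, the most abundant member, differed least among those named, from 6.88 to 19.8. Of the TNF receptors, TNFRSF1A stayed within 0.795 to 1.23 and TNFRSF1B ranged from 0.0914 to 0.692.

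**Figure D2:**
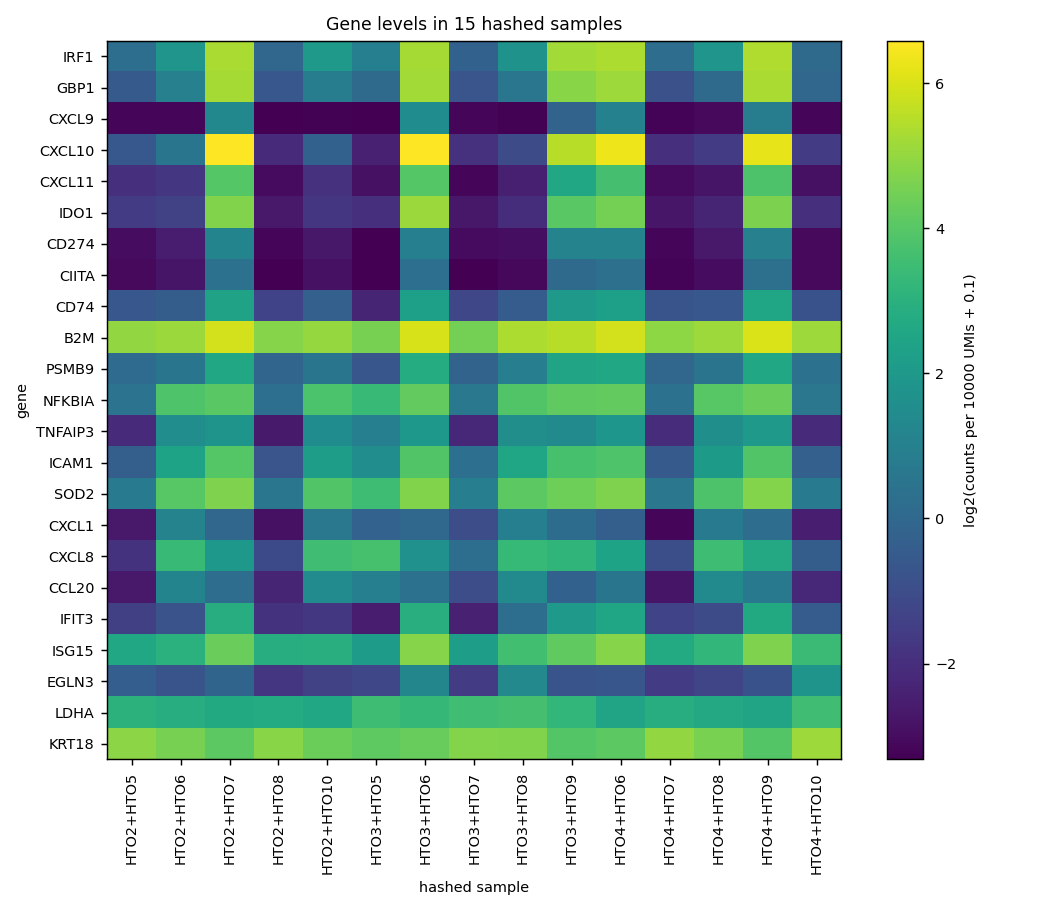
Levels of genes from the fixed lists (rows) in the 15 hashed samples (columns), as log2 of counts per 10000 UMIs plus 0.1. CXCL10 ran from 0.0859 to 95.9 counts per 10000 UMIs, NFKBIA from 1.12 to 20.1 and B2M from 22.8 to 65.0.

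Genes known as type I interferon-stimulated spanned less as a list, 33.2 to 138, with 22 of 28 members meeting the rule. IFIT3 ranged from 0.0687 to 7.49, a ratio of 109 with a counting interval of 42.5 to 400. MX1, an antiviral GTPase, ranged from 0.326 to 3.90. ISG15, a ubiquitin-like modifier, spanned 6.55-fold, IFI27 3.17-fold and BST2 2.22-fold. The lowest list value came from HTO3+HTO5, the smallest sample, and the list span of 4.15 was 2.69 without the 4 hashed samples of fewest cells. IFN-gamma and type I interferon share targets, so the list does not separate the pathways.

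Cell death and p53 genes ranged from 7.71 to 33.8, and 9 of 15 members met the rule. TNFSF10, the death ligand TRAIL, led the list with 0.189 to 13.2, and without it the list span of 4.39 was 2.78. CASP8, the initiator caspase of death receptors, spanned 5.59-fold, CASP4, an inflammatory caspase, 4.36-fold, and CDKN1A, the p21 cell cycle inhibitor, 12.5-fold. BAX stayed within 0.817 to 1.27.

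TGF-beta target genes varied little as a list. Their level ranged from 7.34 to 10.1, or 1.38-fold, although 6 of 15 members met the rule, among them ID3 (0.101 to 0.948). Hypoxia and glycolysis genes ranged from 19.9 to 36.6, and 9 of 18 members met the rule. EGLN3, an oxygen-sensing hydroxylase, spanned 17.1-fold, and LDHA, lactate dehydrogenase A, 2.28-fold. Immediate early and dissociation stress genes ranged from 40.5 to 59.0, with the heat shock protein HSPA8 at 4.85 to 9.59. The unfolded protein and amino acid stress list ranged from 13.1 to 26.8, a 2.05-fold span that was 1.35-fold without cells of clusters 4 and 5 (described below). S phase genes ranged from 2.02 to 7.31. The G2/M list ranged from 0.786 to 7.49, with its lowest value in the 53 cells of HTO3+HTO9, and its 9.53-fold span was 2.90-fold without the 4 hashed samples of fewest cells.

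Markers of cells other than the tumour line were low or had no counts. Epithelial tumour markers were high in every hashed sample, at 42.03 to 92.5, led by the keratin KRT18 at 15.1 to 35.1, and EPCAM, an epithelial adhesion molecule, stood at 2.92 to 4.71. The pooled level of T or NK cell markers was 0.0797, nearly all of it CD69 at 0.0731. CD3D, CD8B and CD2 had 0 counts in the kept cells, as did the endothelial marker KDR and the haemoglobin genes HBB, HBA1 and HBA2. A count of 0 allows a pooled level of up to 0.000679. B cell markers stood at 0.0129, fibroblast markers at 0.0690 and erythroid markers at 0.000453. Myeloid markers reached 0.620, chiefly CD68 at 0.323, and endothelial markers 0.669, chiefly EGFL7 at 0.499. The matrix lists human genes, so mouse host cells were not measured.

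After thinning each cell to 5000 UMIs, which left 3269 cells, genes differed in how many cells had a UMI. B2M was detected in 100% of thinned cells in every hashed sample. CXCL10 was detected in 5.13% (HTO4+HTO8) to 98.6% (HTO3+HTO6) of cells, IDO1 in 2.19% to 95.5% and CD274 in 0% to 62.7%. No CD274 UMI was found in 3 hashed samples, among them the 45 thinned cells of HTO3+HTO5, where a count of 0 allows a share of up to 6.67% of cells with a UMI. CXCL9 reached no more than 38.6% of cells in any hashed sample. NFKBIA was detected in 29.9% to 97.2% of cells and CXCL8 in 6.14% to 83.8%. Without thinning, CXCL10 was detected in 10.2% to 98.3% of cells and NFKBIA in 49.5% to 98.4%. CD274 was then found in 2.82% of cells in HTO3+HTO7 and 6.87% in HTO4+HTO8, and stayed at 0% in HTO3+HTO5. CXCL9 then reached 48.4% of cells in HTO4+HTO6. No cell type that should lack these genes was in the pool, so free RNA cannot be taken off the low shares.

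Across the pooled cells, members of most response lists were positively correlated. For 11 of the 12 response lists the median correlation between members exceeded that of all 10000 random lists matched on expression. It was highest for G2/M genes (0.323) and the IFN-gamma response (0.291), and lower for the TNF/NF-kB response (0.0826). For the immediate early and dissociation stress list it was only 0.0242. Coherence was not computed within hashed samples, so differences between them enter these correlations. The TGF-beta list, at the 80.6 percentile, did not stand apart from random lists. Levels of the IFN-gamma and TNF/NF-kB lists were related across the pooled cells with a Spearman rho of 0.612. Within single hashed samples the rho ranged from 0.0815 to 0.673 with a median of 0.389, and was above 0 in 15 of 15. It was 0.530 to 0.673 in the 5 samples of highest IFN-gamma list level. In the 5 samples of lowest TNF/NF-kB list level it was 0.0815 to 0.216, and in the rest 0.228 to 0.533. The lists share no gene, but whether their members respond to a single cytokine was not tested, so the rho does not separate the pathways. Cells are not replicates, so these are descriptions of this library. Per-cell levels were fitted with mixtures of at most 3 components, and the IFN-gamma list took all 3. The highest was centred at 353 with 23.9% of the cells, and the others, centred at 26.3 and 39.4, overlapped. The TNF/NF-kB list had 2 components, centred at 38.1 and at 153, with 54.9% of cells in the upper, but 3 under several other settings. The hypoxia list had a single component.

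Clustering of the kept cells gave 6 clusters, all of which had UMIs of all 13 epithelial markers. Cluster 3 (925 cells) was led by CXCL11, IDO1, CXCL9 and CXCL10. Its IFN-gamma list level was 342, which was 8.30 times the level in all other cells, with 34 of 35 members at least 1.5-fold higher. Its TNF/NF-kB level was 163 and its MHC class II level 8.06, 6.61 times that elsewhere. Cluster 2 (989 cells) was led by CXCL1, CXCL8, LTB and CCL20. Its TNF/NF-kB level of 153 was near that of cluster 3, with 26 of 44 members higher than elsewhere, but its IFN-gamma level was 37.9. Chemokines of the TNF/NF-kB list differed between these clusters in both directions. CXCL8 stood at 11.9 in cluster 2 and 4.24 in cluster 3, CXCL1 at 2.19 and 0.919, and CCL20 at 2.83 and 1.20. CCL2 and CX3CL1 went the other way, at 1.85 and 0.0385 in cluster 2 and at 2.76 and 0.684 in cluster 3. NFKBIA was similar in both, at 15.99 and 18.1, and IL32 was 2.61 in cluster 2 and 15.6 in cluster 3. Cluster 1 (990 cells), led by the growth factor genes BDNF and BMP4, had low levels of both lists, 24.0 and 40.4. Its epithelial level, 84.3, was above that of cluster 3 (47.5), with KRT19 at 17.7 and 7.37.

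Cluster 4 (257 cells) was led by cell cycle genes such as SPC25, AURKB and MKI67, with all 19 G2/M members and all 20 S phase members higher than elsewhere. Its median depth was 17998 UMIs, and 19.1% of its cells had no clear hashtag pair, against 6.36% to 14.9% in the other clusters. Cluster 5 (192 cells) was led by HSPA1A, a heat shock protein, SESN2 and DDIT3, a transcription factor of the unfolded protein response. Its unfolded protein and amino acid stress level was 76.9, or 5.30 times that elsewhere, and it held cells of all 15 hashed samples. The immediate early and dissociation stress list, which holds HSPA1A, was also higher in cluster 5. It stood at 73.7, or 1.64 times that elsewhere, with 9 of 17 members higher and 0 lower. Cluster 6 (185 cells) was led by SOX9-AS1, MBNL2 and NFATC2, with LGALS1 at 11.95, and had the lowest median depth of 7736 UMIs and the highest median mitochondrial share of 16.2%. None of its response lists was over 1.10 times the level elsewhere. Of the marker lists, fibroblast markers stood at 0.271 (0.195 to 0.368) against 0.0619 elsewhere. B cell markers stood at 0.0596 (0.0272 to 0.113) against 0.0112. Both lists were near the floor, with no member at a mean of at least 0.05. Epithelial, myeloid and T or NK cell markers were not higher than elsewhere. Clusters were made from the same counts as these levels, so the differences are descriptions without a test. No cell type name beyond tumour cells was given to any cluster.

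**Figure D3:**
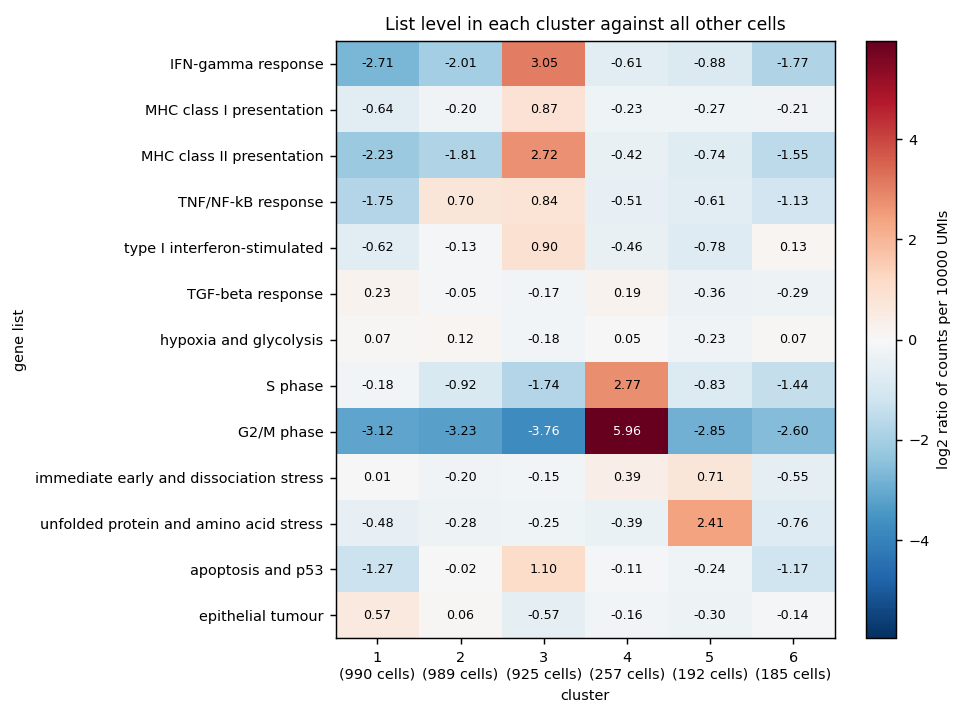
Log2 ratio of the summed counts per 10000 UMIs of 13 gene lists (rows) in each of 6 clusters (columns) against all other cells, with the ratio printed in each cell. The IFN-gamma list was 8.30 times as high in cluster 3 as elsewhere, and the unfolded protein list 5.30 times as high in cluster 5.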

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

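The hashtag HTO1, which belonged to no pair, had 97 counts over all barcodes and at most 2 in any barcode, a signal above 0 in a tag that no hashed sample carried. Among kept cells with no clear pair, which no value per hashed sample uses, the IFN-gamma list level was 110 counts per 10000 UMIs, and their median depth was 12899 UMIs against 11509.5 in kept cells with a pair. In the 1731 removed barcodes the IFN-gamma list stood at 70.9, against 121 in kept cells. The TNF/NF-kB list (72.3) and the hypoxia and glycolysis list (18.8) were also below their levels in kept cells (111 and 26.9). The removed barcodes had a median of 29.2% mitochondrial UMIs, against 13.1% in kept cells. Of these barcodes, 1536 had a clear pair, and their IFN-gamma list level ran from 12.3 in HTO3+HTO7 to 219 in HTO2+HTO7.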

How the results depend on the processing

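The pair rule, spans over hashed samples, the relation within hashed samples and clustering of paired cells only were chosen after seeing the data. Of the kept-cell filters, a limit of 10% mitochondrial UMIs left 732 cells. Requiring 10 times the second hashtag placed 4 cells by the single-hashtag rule, HTODemux called 33 singlets, and the pair rule placed 3144 cells at a ratio of 3 and 2995 at a ratio of 10. Pooled levels moved with the total and the members by construction. The IFN-gamma list (121) was 163 without mitochondrial and ribosomal protein genes in the total, 112 over all barcodes and 95.2 without CXCL10, and the TNF/NF-kB list (111) was 149, 104 and 95.8 without LCN2. The IFN-gamma span of 20.8 became 15.6 without CXCL10 and 18.1 without the 4 smallest hashed samples. The TNF/NF-kB span of 6.97 became 6.33 over all barcodes, 8.79 without LCN2 and 7.37 without clusters 4 and 5. For the other 10 lists, all 30 pooled levels moved and 43 spans stayed within the main interval while 17 did not. The spans that moved by over 1.5 times stand beside their lists in the report, apart from MHC class II genes without CD74 (22.5) and G2/M genes over all barcodes (5.78) and without clusters 4 and 5 (2.77). The rho of the IFN-gamma and TNF/NF-kB lists was 0.572 with z scores and 0.389 as the median within hashed samples. Coherence stayed on its side of the threshold percentile for all 12 lists under all 3 alternatives. The fits allowed at most 3 mixture components, so the 3 of the IFN-gamma list under all 4 alternatives do not show a stable number, and the TNF/NF-kB list had 3 instead of 2 under 3 of 4. Leiden resolution 1.0 gave 11 clusters, the other settings 4 to 7. The ratio of the highest to the lowest cluster was 14.3 for the IFN-gamma list and 12.9 to 15.9 under alternatives. Beyond changes made by construction, the cause was not tested. Removing Scrublet doublets was void, as none was marked. Alternatives of the planned tests between treatments were not run, since no treatment map was at hand. No paired analysis was possible because the hashed samples carry no treatment or tumour number. Depth limits small samples most: in HTO3+HTO5, with 582102 UMIs, 3 counts equal 0.0515 per 10000 UMIs.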

Other observations

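Genes outside the fixed lists that spanned widely over the hashed samples were chosen after their values were seen. GCH1, the rate-limiting enzyme of tetrahydrobiopterin synthesis, ranged from 0.0107 to 1.72 counts per 10000 UMIs, the lower value resting on 2 counts. TNFSF13B, which encodes the B cell survival factor BAFF, ranged from 0.0172 (a single count) to 1.60, RNF213 from 0.937 to 12.9 and NNMT, nicotinamide N-methyltransferase, from 0.534 to 5.45. RIPK2, a kinase of innate signalling, ranged from 0.291 to 5.37. BMP4 went from 0.0267 (2 counts) in HTO4+HTO9 to 1.97 in HTO2+HTO5, and ANGPTL4, a hypoxia-inducible lipase inhibitor, reached 3.42 in HTO4+HTO10. Of 9427 genes with a mean of at least 0.05, 947 (10.0%) met the span rule, 169 of them in a response list.

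All tests below were chosen after the data were seen. For those of the IFN-gamma list without CXCL10, and of the hypoxia list without LDHA and without clusters 4 and 5, the bounds were written before the test was run. The bounds of the other tests were written afterwards. The IFN-gamma list levels of the 15 hashed samples, which carry no treatment, fell into 2 separate ranges. The levels were 24.0 in HTO2+HTO5, 34.2 in HTO2+HTO6, 354 in HTO2+HTO7, 19.9 in HTO2+HTO8, 33.2 in HTO2+HTO10, 22.1 in HTO3+HTO5, 361 in HTO3+HTO6 and 17.3 in HTO3+HTO7. They were 38.5 in HTO3+HTO8, 246 in HTO3+HTO9, 321 in HTO4+HTO6, 21.0 in HTO4+HTO7, 30.7 in HTO4+HTO8, 337 in HTO4+HTO9 and 28.5 in HTO4+HTO10. The widest gap on the log2 scale was 2.67, with 5 samples above it. Without CXCL10 the gap was 2.39 with the same 5 samples above, which argues against CXCL10 alone carrying it. The highest median UMI count was 1.13 times the lowest, which argues against depth per cell, although these medians were known when the bound was set. No biological explanation was tested, since no label gives the treatment of a hashed sample.

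The TNF/NF-kB list also left a gap, at another place. Its levels were 35.6 in HTO2+HTO5, 134 in HTO2+HTO6, 159 in HTO2+HTO7, 24.5 in HTO2+HTO8, 123 in HTO2+HTO10, 97.4 in HTO3+HTO5, 166 in HTO3+HTO6 and 36.3 in HTO3+HTO7. They were 142 in HTO3+HTO8, 139 in HTO3+HTO9, 150 in HTO4+HTO6, 36.2 in HTO4+HTO7, 131 in HTO4+HTO8, 171 in HTO4+HTO9 and 32.8 in HTO4+HTO10. The widest gap was 1.42 on the log2 scale, with 10 samples above it and 5 below. These ranges are values of unlabelled samples, and no treatment is read from them.

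Hypoxia and glycolysis levels lay in 2 narrower ranges that cut across those of the IFN-gamma list. HTO3+HTO5 (33.6), HTO3+HTO6 (29.8), HTO3+HTO7 (30.4), HTO3+HTO8 (35.1), HTO3+HTO9 (29.6) and HTO4+HTO10 (36.6) lay above a gap of 0.33 on the log2 scale. HTO2+HTO5 (23.5), HTO2+HTO6 (22.3), HTO2+HTO7 (21.8), HTO2+HTO8 (22.2), HTO2+HTO10 (20.5), HTO4+HTO6 (20.6), HTO4+HTO7 (21.9), HTO4+HTO8 (20.2) and HTO4+HTO9 (19.9) lay below it. The same 6 samples stayed above the gap without LDHA, where the gap was 0.29, and without clusters 4 and 5, where it was 0.31, which argues against LDHA alone and against cycling or stressed cells as the whole cause. Only 3 of the 6 were among the 6 of highest mitochondrial share, which argues against that share as the whole cause. The split followed a shared hashtag in part, with all 5 pairs of HTO3 above the gap, 1 of 5 pairs of HTO4 and 0 of 5 pairs of HTO2. Handling shared by samples of 1 hashtag, or a difference between the 5 source tumours, may be involved and stays untested, since no label ties hashtags to either.

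CXCL10 in the lower range was not uniform, at 1.34 in HTO2+HTO6, 0.749 in HTO2+HTO10 and 0.558 in HTO2+HTO5. The other 7 samples below the gap held 0.129 (HTO2+HTO8), 0.0859 (HTO3+HTO5), 0.165 (HTO3+HTO7), 0.377 (HTO3+HTO8), 0.154 (HTO4+HTO7), 0.236 (HTO4+HTO8) and 0.233 (HTO4+HTO10). Over thinned cells of these 3 samples the variance of CXCL10 counts was at least 13.8 times their mean, which argues against free RNA at 1 even level as the whole cause. HTO2+HTO5 held 2 cells of cluster 3, HTO2+HTO6 held 3 and HTO2+HTO10 held 1, and without them CXCL10 fell to 0.136, 0.667 and 0.251. High cells also lie in other clusters: in HTO2+HTO6, 7 of 320 cells held 435 of 535 CXCL10 counts. Without the 2% of cells with most CXCL10 counts in each sample, HTO2+HTO6 stood at 0.258 (0.210 to 0.314), 1.42 times the highest of the other 7. HTO2+HTO5 stood at 0.110 and HTO2+HTO10 at 0.205. The other 7 so trimmed ran from 0.0704 in HTO3+HTO5 to 0.181 in HTO3+HTO8. The excess in HTO2+HTO5 thus rested on a few cells. Whether a few cells account for the whole of the difference in HTO2+HTO6 and HTO2+HTO10 stays open. Whether such cells were given the wrong pair or were mixed droplets was not tested.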
